A study of Rattus norvegicus with 11 samples.

How the data were processed

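Poly(A)-selected RNA from rat ipsilateral spinal cord was sequenced as directional libraries, from 1 ug of total RNA per library, per the labels' protocols. The rats were adult males of 350 to 400 g. The 11 libraries analysed were grouped by the group label of each sample: 3 naive, 5 given paclitaxel with an electrode and no stimulation (sham), and 3 given paclitaxel, an electrode and spinal cord stimulation (SCS). The titles mark the sham group with the letter X and the stimulated group with S, a letter that could also stand for sham, and the group label was followed. Replicate numbers came from the sample titles, and the stimulated libraries carry the numbers 1, 2 and 5.

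The deposited table holds whole-number counts per Ensembl rat gene ID, which the authors made before deposit. The submitters' processing notes name HISAT2, featureCounts, DESeq2 and the genome build rn6. Their versions, the annotation release, the strand setting of the counting and any filter are not given in the sources used here. Without the strand setting, the counts of overlapping and antisense genes are uncertain, as are those of near-identical gene copies that share reads. Columns were assigned to samples by the sample title held in each column name, and 17 further sample columns were not used here.

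The table lists 32623 gene IDs and does not pair them with gene names. The gene table used here holds 47357 rows, of which 0 carry an Ensembl ID, so 0 IDs were matched to a symbol. For that reason the 37 gene lists (1036 symbols) fixed before the data were examined could not be tested. Shares of counts from the mitochondrial genome, haemoglobin and ribosomal proteins could not be computed either. The rule for naming genes, also fixed in advance, took the genes with the largest fold changes and smallest p-values among those past the threshold whose groups did not overlap and whose mean was at least 1 CPM (counts scaled to a common library total), with a fixed set of symbols, and passed over bare IDs. It therefore named no gene. The 4 IDs printed were chosen after their values were seen. They have the highest and the lowest log2 fold change among the non-overlapping genes past the threshold with a mean CPM of at least 1, in sham against naive and in stimulated against sham.

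Genes with low counts were removed with filterByExpr of edgeR 4.0.16 (R 4.3.3) on the 3 groups, which left 15758 genes, or 48.3% of the IDs. In each library they held at least 99.926% of the counts. Library sizes were scaled by TMM factors. All 11 libraries entered 1 quasi-likelihood fit with a term per group and no covariate (estimateDisp, glmQLFit with robust estimation, glmQLFTest), with 8 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 on the adjusted p. Every adjusted p in the text comes from this edgeR test unless another tool is named. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. CPM values used the TMM-scaled library sizes, and log2 CPM used a prior count of 2. The biological coefficient of variation was 11.2%. The labels number the samples but do not state that each came from a separate rat, so p-values measure the spread between these samples. That spread was pooled over the 3 groups. Estimated alone, it was 6.96% in naive, 11% in sham and 14.4% in stimulated libraries, so p-values of stimulated against sham may be too small.

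Total counts were 11243288 to 56775931 per library. The chi-square statistic per degree of freedom between libraries of 1 group was 5.02 to 29.1, so no pair agreed within sampling noise. The fit was tested on simulated counts with known fold changes. For sham against naive (15628 genes) it recovered 66% of genes changed 1.5-fold and 82% of those changed 2-fold. For stimulated against sham (15622 genes) the shares were 62.6% and 78.6%, and for stimulated against naive (15628 genes) they were 59% and 81.6%. False calls made up 5.44% to 5.73% of the calls. The simulated genes varied independently and with the same spread in each group. In the data the spread was 6.96% in naive and 14.4% in stimulated libraries, so these rates need not hold there.

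Totals, detected genes and the share of the top 20 genes were compared by two-sided exact permutation tests, adjusted over 9 tests. Contrasts that share libraries were set beside 100 simulated sets of unchanged groups, in which each gene varied independently. Their top genes by p were taken in lists as long as the real ones. The sham libraries were also split between both contrasts in all 10 ways. Alternatives fixed before the data were examined covered scaling, the filter on low counts, the tool (DESeq2 1.42.0, limma 3.58.1 with and without sample quality weights), a fold threshold, the adjusted p threshold, fits of 2 groups only, a surrogate variable (sva 3.50.0), the replicate number as a block, and leaving out each library. Thinning every library to the smallest total, and splits with 3 sham libraries in sham against naive, were added after the data were seen.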

Results

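The libraries measured gene expression in the ipsilateral spinal cord of male rats in 3 groups. Naive rats (3 libraries) had neither drug nor electrode. The other rats received paclitaxel, a microtubule-stabilising chemotherapy drug that can cause painful neuropathy, at 1.5 mg/kg into the peritoneum on days 1, 3, 5 and 7. They had an electrode for spinal cord stimulation (SCS), an electrical treatment for pain, which was left off in the sham group (5 libraries). In the stimulated group (3 libraries) it was run at 50 Hz with 0.2 ms pulses. Values of n count libraries, which are named naive 1 to 3, sham 1 to 5, and SCS 1, SCS 2 and SCS 5.

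Total counts ran from 17401720 to 56775931 in the naive libraries, from 11243288 to 22144967 in the sham libraries and from 18633243 to 29395233 in the stimulated libraries. Naive libraries had counts in 19575 ± 884 genes (SD, n = 3), sham libraries in 18742 ± 442 (SD, n = 5) and stimulated libraries in 19354 ± 249 (SD, n = 3). The top 20 genes took 13.6%, 14.2% and 13.9% of the counts in these groups. None of the 9 differences in totals, detected genes or top-gene share passed the two-sided exact permutation test (smallest adjusted p 0.241). For 3 against 3 libraries that test cannot go below 0.1 before adjustment, and for 3 against 5 not below 0.0179. A full separation in a single test could therefore not pass over 9 tests, so depth may still differ. Mean totals in sham were 0.505 of those in naive libraries (unadjusted exact permutation p 0.0536). With any 1 of these libraries left out the ratio was 0.409 to 0.794, and it was highest without naive 3, the largest library. Along the first principal component of log2 CPM, with 35.7% of the variance, naive libraries lay between -28.9 and -23.9, sham libraries between -23.3 and 15.5, and stimulated libraries between 19.2 and 50.7.

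**Figure D1:**
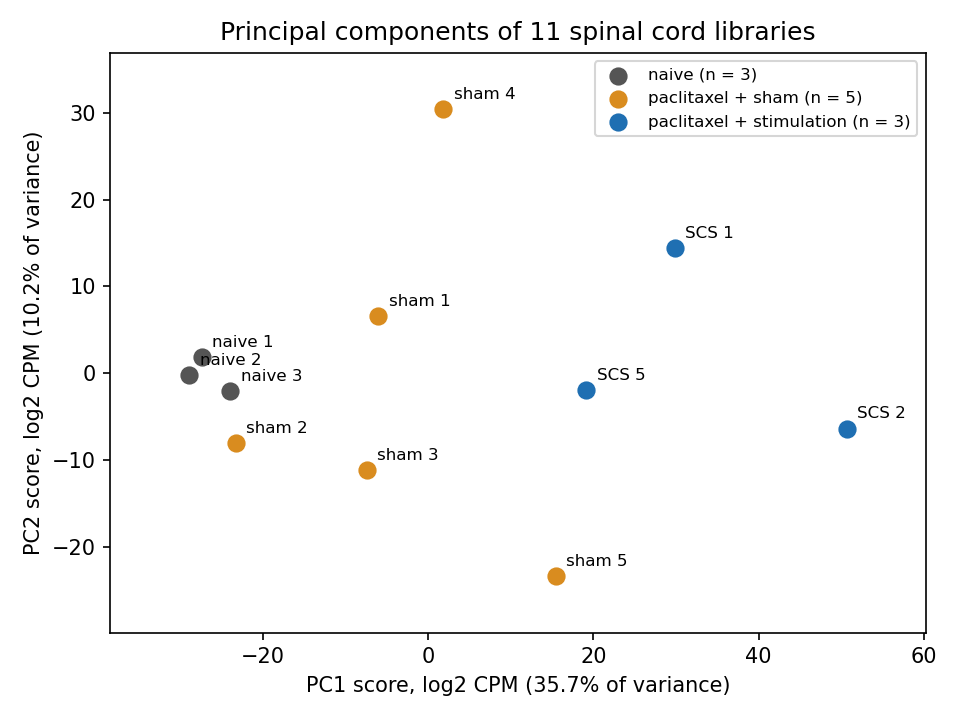
First against second principal component of log2 CPM over the tested genes, 1 point per library, coloured by group, with the share of variance on each axis. The sham libraries spread between the naive and the stimulated libraries along the first component (35.7% of variance).

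The comparison of sham with naive libraries shows what differed after paclitaxel and electrode placement together, since no group analysed here had only one of them. In the sham libraries 21 genes rose and 1 fell, out of 15758 tested. The changes were large: the 21 higher genes had a median log2 fold change of 2.14, and 20 of them rose at least 2-fold. ENSRNOG00000014350 rose from 4.17 ± 0.18 CPM in naive libraries (SD, n = 3) to 70.3 ± 28.4 CPM in sham libraries (SD, n = 5), a log2 fold change of 4.07 ± 0.35 (SE, edgeR adjusted p = 0.00395). ENSRNOG00000023387, the only gene that fell, went from 13.9 ± 8.8 CPM (SD, n = 3) to 0.556 ± 0.088 CPM (SD, n = 5), a log2 fold change of -4.62 ± 0.52 (SE, edgeR adjusted p = 0.00534). Naive 3 held this gene at 3.71 CPM, against 19.8 CPM in naive 1 and 18.1 CPM in naive 2.

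In all 22 genes the sham and naive libraries did not overlap in log2 CPM. Of all tested genes, 7.03% did not overlap, where chance gives 3.57%. An unadjusted p under 0.05 was found for 1257 genes, where 787.9 would be so by chance. The count was 10, 6 and 11 without naive 1, naive 2 and naive 3, 56 without sham 2 and 12 without sham 4, and it was 133 with DESeq2, 44 with limma-voom and sample quality weights, and 9 with a surrogate variable. The call of ENSRNOG00000023387 was lost with limma-voom (adjusted p 0.475), with quality weights (0.36), in the fit of 2 groups only (0.0775) and with a surrogate variable (0.217), over a range of 7.38e-21 to 0.475 in 24 alternatives.

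**Figure D2:**
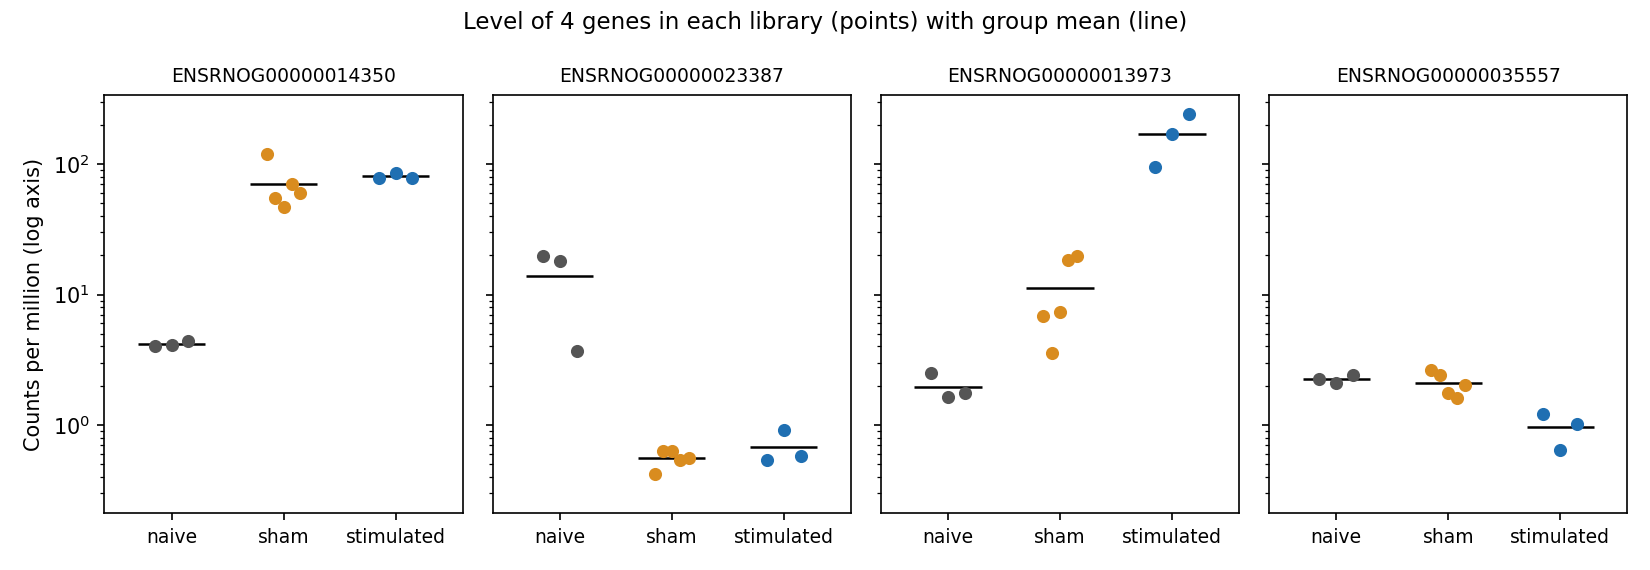
CPM of the 4 printed genes on a log axis, 1 point per library, with a line at the mean of each group. ENSRNOG00000014350 was at 4.06 to 4.38 CPM in naive libraries and 46.8 to 119 CPM in sham libraries, and ENSRNOG00000013973 was at 3.54 to 19.7 CPM in sham libraries and 95.7 to 242 CPM in stimulated libraries.

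The comparison of stimulated with sham libraries asks what stimulation changed in rats that all had drug and electrode, with the groups as the group label gives them (the title letter S of the stimulated group is open to another reading). In the stimulated libraries 472 genes rose and 91 fell, so 83.8% of the 563 changed genes were higher. The genes that rose did so by a median log2 fold change of 0.75 (interquartile range 0.48 to 1.11), and 149 of them rose at least 2-fold. The genes that fell did so by a median of -0.30, 1 of them at least 2-fold, and they were more abundant, at a median of 69.9 CPM against 15.2 CPM for the genes that rose. ENSRNOG00000013973 rose from 11.1 ± 7.3 CPM in sham libraries (SD, n = 5) to 169 ± 73 CPM in stimulated libraries (SD, n = 3), a log2 fold change of 3.94 ± 0.50 (SE, edgeR adjusted p = 0.0127).

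The naive libraries held ENSRNOG00000013973 at 1.97 ± 0.46 CPM (SD, n = 3), and its difference between sham and naive did not pass (log2 fold change 2.54 ± 0.71, SE, edgeR adjusted p = 0.421). That difference passed with DESeq2 alone of 24 alternatives (log2 fold change 2.51, adjusted p 0.00414, the lowest of a range up to 0.9997), and its sham libraries, at 3.54 to 19.7 CPM, did not overlap the naive libraries, at 1.63 to 2.50 CPM. ENSRNOG00000035557 fell from 2.08 ± 0.42 CPM in sham libraries (SD, n = 5) to 0.959 ± 0.293 CPM in stimulated libraries (SD, n = 3), a log2 fold change of -1.11 ± 0.26 (SE, edgeR adjusted p = 0.036). It was at 2.25 ± 0.16 CPM in naive libraries (SD, n = 3). Its call was lost in 13 of 24 alternatives (adjusted p 0.00764 to 0.765), among them without any 1 of naive 1, naive 2, naive 3, SCS 2, SCS 5, sham 1, sham 2 and sham 3 (0.0506 to 0.188). The call of ENSRNOG00000013973 was lost without SCS 2 (adjusted p 0.0598) and in 2 other alternatives of 24 (range 6.41e-09 to 0.649).

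Among the 563 genes, 503 did not overlap between the stimulated and sham libraries. Over all tested genes 10.2% did not overlap, where chance gives 3.57%. An unadjusted p under 0.05 was found for 3174 genes, where 787.9 would be so by chance, and there the balance was closer, with 1870 higher and 1304 lower (58.9% higher). The higher share was 74.6% at an adjusted p of 0.1 and 96.2% with a fold threshold of 1.5. The number of changed genes was 36 without SCS 2 and 943 without SCS 5, it was 175, 224, 230 and 1057 without sham 1, sham 2, sham 3 and sham 5, and 362, 369 and 284 without naive 1, naive 2 and naive 3, which enter the shared estimate of spread. It was 1136 with DESeq2, 1243 at an adjusted p of 0.1, 316 with a fold threshold of 1.5, 140 in the fit of 2 groups only and 1 with a surrogate variable. Of the variance of that variable, 75.4% lay between the groups. A similar count could hold other genes. Of the 563, 311 passed again among the 510 without SCS 1. With limma-voom and quality weights 396 did among 491, and with median-ratio scaling 562 did among 581.

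**Figure D3:**
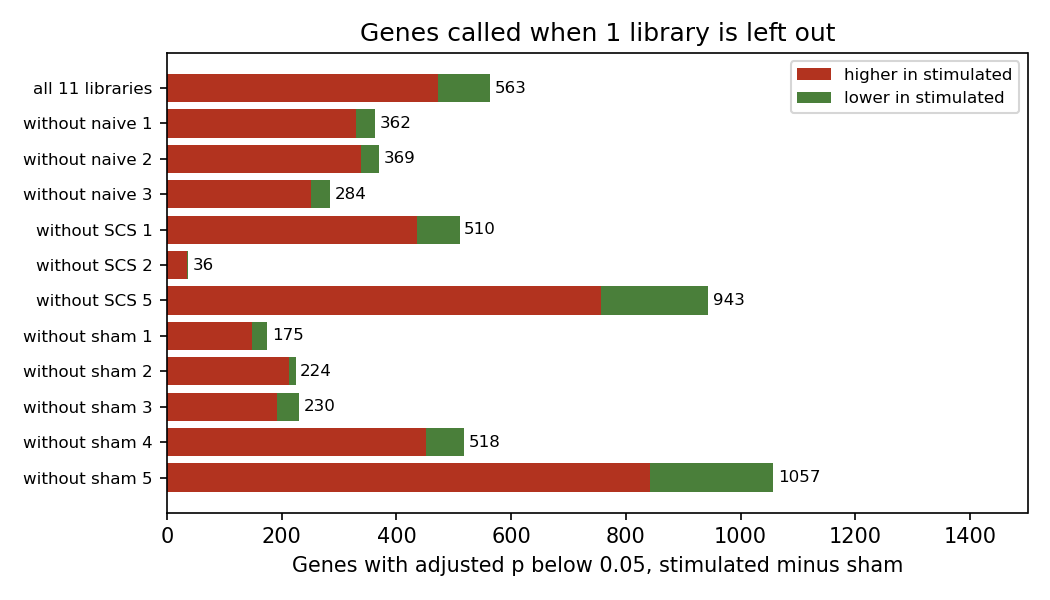
Number of genes with adjusted p below 0.05 in stimulated against sham, higher genes in red and lower genes in green, with all 11 libraries and with each library left out in turn. The count was 563 with all libraries, 36 without SCS 2 and 1057 without sham 5.

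Stimulated and naive libraries differed in drug, electrode and stimulation together. In the stimulated libraries 1584 genes rose and 758 fell, or 14.9% of the tested genes. The genes that rose did so by a median log2 fold change of 0.80, 647 of them at least 2-fold. The genes that fell did so by a median of -0.30, 13 of them at least 2-fold. ENSRNOG00000014350 was at 80.6 ± 4.5 CPM in stimulated libraries (SD, n = 3), a log2 fold change of 4.26 ± 0.37 over naive (SE, edgeR adjusted p = 0.000421).

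Of the 2342 changed genes, 2300 did not overlap between the stimulated and naive libraries. Over all tested genes 36.3% did not overlap, where chance gives 10%. An unadjusted p under 0.05 was found for 4620 genes, where 787.9 would be so by chance. The count was 1226, 1018 and 1199 without naive 1, naive 2 and naive 3 and 1091 without SCS 2, and it was 1031 with a fold threshold of 1.5 and 1 with a surrogate variable. The call of ENSRNOG00000014350 was lost with the surrogate variable alone of 24 alternatives (log2 fold change 4.21, adjusted p 0.618, range 1.06e-35 to 0.618).

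The design also asks whether genes that differed in sham libraries moved the other way under stimulation. By the edgeR test 0 genes passed in both contrasts with opposite signs, and 2 passed in both with the same sign. At an unadjusted p under 0.05 in both contrasts, 51 genes had opposite signs and 501 the same sign. Of the genes that rose in stimulated libraries, the median log2 fold change in sham against naive was 0.31, and of those that fell it was -0.01. The 21 genes that rose in sham libraries had a median log2 fold change of 0.12 in stimulated against sham (range -1.77 to 1.04), and ENSRNOG00000014350 was at 0.19 ± 0.26 (SE, edgeR adjusted p = 0.751).

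Independent lists of these sizes would share 0.151 genes with opposite signs and 0.635 with the same sign, and the top 22 and top 563 genes of 100 simulated sets of unchanged groups shared a mean of 7.49 with opposite signs (2 to 11) and 0.11 with the same sign. Of the 22 genes changed in sham against naive, 13 had the same sign in stimulated against sham. Of the 563 genes changed in stimulated against sham, 490 (87%) had the same sign in sham against naive. In the simulated sets, which hold no changed gene, the shared sham libraries brought that share of the top 563 genes down to 16.4% (range 12.3% to 20.2%). Genes picked for noise alone lean further to opposite signs than changed genes would. The simulated 16.4% and 7.49 therefore overstate the gap to the real lists. Across genes, which are not independent replicates, both sets of fold changes had a covariance of 0.0219 (Pearson r 0.18), against -0.0194 in the simulated sets (range -0.0224 to -0.0173), a difference of 0.0413. With the sham libraries split so that the contrasts shared none, no split gave a gene with opposite signs, and the median covariance was 0.0493 with 2 and 0.0494 with 3 libraries in sham against naive. With 2 libraries there the same-sign share was 92.5% to 96.2%, over 14 to 957 changed genes in stimulated against sham. With 3 there that contrast had 0 to 644 changed genes, too few in some splits for a share. The count with opposite signs was 5 with DESeq2 (57 with the same sign), 0 with limma-voom, 1 with quality weights and 1 without naive 3. The covariance was 0.00336 without SCS 2, 0.0126 with quality weights and -0.301 with no filter on low counts.

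Of the 22 genes changed in sham against naive, 21 also passed in stimulated against naive, with the same sign. Because both contrasts use the naive libraries, the top 22 and top 2342 genes of simulated unchanged groups shared a mean of 16.2 with the same sign (12 to 20), and independent lists would share 2.16. Stimulated against sham and stimulated against naive shared 538 genes with the same sign and 0 with opposite signs by the edgeR test (1 gene at an unadjusted p under 0.05), against a mean of 282 with the same sign (253 to 316) in simulated lists of the same lengths and 51.8 for independent lists. The 3 naive and 3 stimulated libraries were too few to split, so part of both overlaps may come from the shared libraries.

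**Figure D4:**
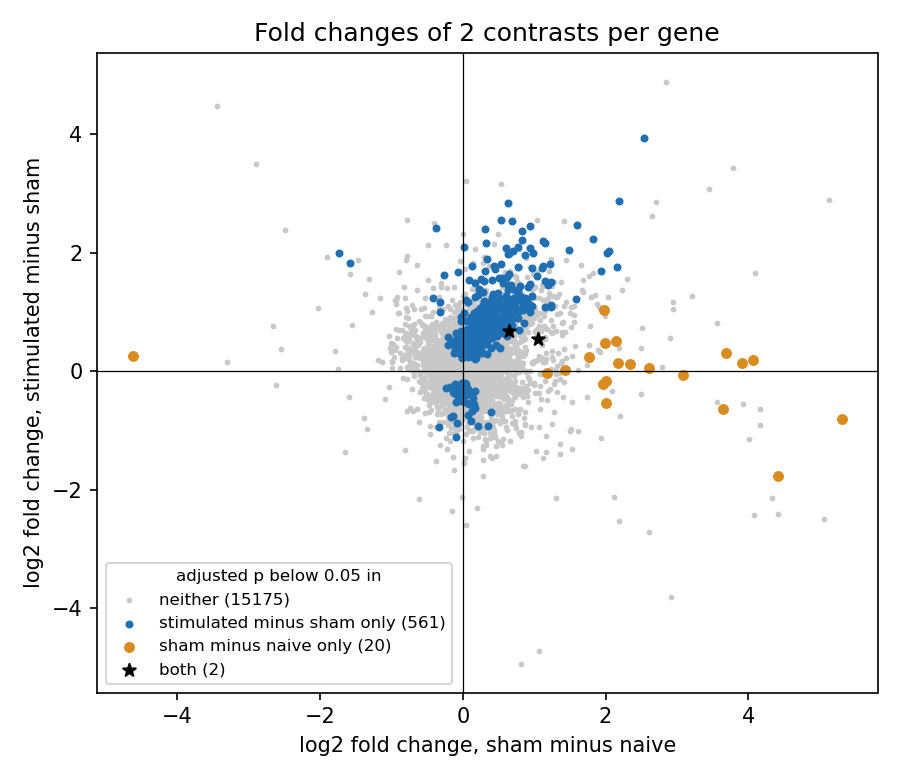
Log2 fold change per gene in stimulated against sham (y axis) over that in sham against naive (x axis), coloured by the contrast in which the gene passed an adjusted p of 0.05. The 2 genes that passed in both lie in the upper right, and most genes that rose in stimulated libraries lie to the right of 0, at a median of 0.31 on the x axis.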

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

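The thinned libraries and the splits with 3 sham libraries in sham against naive were chosen after the data were seen. Leaving out 1 library at a time gave 6 to 56 changed genes in sham against naive, 36 to 1057 in stimulated against sham, 1018 to 2786 in stimulated against naive, 0 to 1 genes with opposite signs, and a covariance of 0.00336 to 0.0301. The low ends came without naive 2 for both contrasts with naive and without SCS 2 for stimulated against sham and the covariance. In the same order of contrasts, other scalings gave 22, 581 and 2272 genes (median ratio) and 21, 561 and 2376 (upper quartile), and thinning gave 15, 492 and 1936. DESeq2 gave 133 and 1136 genes in the contrasts with sham and 5 genes with opposite signs. Quality weights gave 44 genes in sham against naive, 1 gene with opposite signs and a covariance of 0.0126. The cause was not tested for either tool. By construction a fold threshold of 1.5 lowered the counts with stimulated libraries to 316 and 1031, and an adjusted p of 0.1 raised stimulated against sham to 1243. The fit of 2 groups only gave 140 there, against 27 in sham against naive and 1996 in stimulated against naive. For the 140 it left out the naive libraries, whose spread was the lowest. Their biological coefficient of variation was 6.96%, against 11% in sham and 14.4% in stimulated libraries. Why the count fell was not tested.

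With a surrogate variable 9, 1 and 1 genes passed, and 75.4% of its variance lay between the groups. Of the genes called without it, 8 of 22, 0 of 563 and 0 of 2342 passed again. Fold changes moved less than the counts: in sham against naive ENSRNOG00000014350 stood at 4.05 and ENSRNOG00000023387 at -4.72, in stimulated against sham ENSRNOG00000013973 at 3.39 and ENSRNOG00000035557 at -0.67, and the covariance was 0.0226. The cause was not tested. With no filter on low counts the covariance was -0.301 over 23034 genes, and 0.0219 over the 15758 genes that pass the filter, so the low-count genes turned its sign. With the sham libraries split it was 0.0493 and 0.0494. With the replicate number as a block, 9, 5 and 672 genes passed, with 4 residual degrees of freedom. Correlations of same-numbered deviations ran from -0.17 to 0.13, and not every sample correlated best with its own number, so the numbers were not taken as pairs. Under the block ENSRNOG00000014350 in sham against naive had an adjusted p of 0.0861, the only one of 24 alternatives (1.92e-40 to 0.0861) past 0.05. No fold change of a printed gene that passed the test changed sign. Other settings for the gene lists, fixed in advance, were not run, since 0 IDs were matched. At the present depth and number of libraries the simulations recovered 62.6% of 1.5-fold and 78.6% of 2-fold changes in stimulated against sham. Depth was not varied in them.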

Other observations

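The tests of the position of the sham libraries, of exchanged group names, of the choice of scaling factors and of the balance of directions without SCS 2 were chosen after the result was seen, as was the count for the 500 lowest genes, and thinning was added after the first counts of changed genes were seen. Within-group spread differed in size, with a biological coefficient of variation of 6.96% in naive, 11% in sham and 14.4% in stimulated libraries, a difference that was not tested. Genes under 0.5 CPM in every library of 1 group and over 2 CPM in every library of another were rare. There was 1 in sham against naive, 0 in stimulated against sham and 2 in stimulated against naive, all over 2 CPM in the first group named.

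Most genes that changed in stimulated against sham were higher (83.8% of the 563, and 58.9% of the 3174 at an unadjusted p under 0.05). Lower depth of the sham libraries was argued against by thinning, which left 492 genes, 85.6% of them higher. The choice of scaling factors moved the share of higher genes by at most 0.771 percentage points. SCS 2 carries much of the count, but against SCS 2 alone as the source of the direction, 35 of the 36 genes called without it (97.2%) and 1280 of the 1987 at an unadjusted p under 0.05 (64.4%) were higher, and the 500 genes highest in SCS 2 against sham 1 and sham 2 had a median log2 difference of 0.418 in SCS 5 and 0.81 in SCS 1 against sham 3 to 5 (the 500 lowest had -0.10 and -0.07). An effect of stimulation is a hypothesis that stays open beside a change in cell makeup, which was not tested without gene names. A shift common to most genes also stays open. It cannot be told apart because scaling itself holds the median of all genes (-0.0132) near 0. Differences between samples other than stimulation stay open too. On the first principal component the sham libraries, all unstimulated, already ran from -23.3 to 15.5, against 19.2 to 50.7 in stimulated libraries.

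The real grouping gave the highest count among the 56 splits of 8 libraries in stimulated against sham. Only that 1 split reached 563, and the highest other gave 137, which argues against chance. It cannot exclude chance, since 1 of 56 is the smallest share these splits can give, with no adjustment over contrasts. Splits that mix the groups also count a real difference as spread, which lowers their counts. In sham against naive 1 of 56 splits reached 22 and the highest other gave 4, which argues against chance with the same limits. In stimulated against naive 10 splits are too few for a share under 0.05, with 2342 genes in 1 split, the real one, and 1 in the highest other.

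Over the 15758 genes that passed the filter on low counts, fold changes in stimulated libraries leaned further from naive rather than back toward it (Pearson r 0.18). With no filter the covariance turned to -0.301 over 23034 genes. The lean was not general: of the 22 genes changed in sham against naive, 13 kept their sign in stimulated against sham. Genes that fell in stimulated libraries had a median log2 fold change of -0.01 in sham against naive. Shared sham libraries gave a negative covariance in simulated sets (-0.0224 to -0.0173). The observed 0.0219 lies above that range, though it was 0.00336 without SCS 2. The simulated genes varied independently, so that range leaves out variation common to many genes and is too narrow to decide. With the sham libraries split, the covariance was positive in every split. It ran from 0.0102 to 0.0865 with 2 and from 0.0135 to 0.0826 with 3 libraries in sham against naive. The sample titles mark the stimulated group with the letter S, which could also stand for sham. An exchange of the names of both paclitaxel groups would turn a move away from naive into a move back. Then 538 genes would move in opposite directions, where simulated lists of the same lengths gave a mean of 282 (253 to 316) from the shared libraries. Such an exchange and an added effect of stimulation cannot be told apart by any value here, since without gene names no gene of known response could be looked up. A swap of single libraries is argued against by the 56 splits, of which no other gave more than 137 genes.

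The sham libraries may lie part of the way from naive to stimulated. On an axis built from naive and stimulated libraries, with naive at 0 and stimulated at 1, the 5 sham libraries had a mean position of 0.417 ± 0.240 (SD, n = 5), from 0.0755 in sham 2 to 0.734 in sham 5. Without SCS 2 the mean was 0.485 (0.0739 to 0.814). Libraries simulated at 0.4 were placed at 0.376. Why sham libraries differ so much in position was not tested.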
